A study of Homo sapiens with 12 samples.

How the data were processed

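The data were 12 RNA-seq libraries from KOLF2.1J, an established human induced pluripotent stem cell (iPSC) line, in a version that carries a doxycycline-inducible cassette of 6 transcription factors at the CLYBL locus (SPI1, which encodes PU.1, among them). Undifferentiated cells (iTF-iPSCs) and cells at day 18 of factor-driven differentiation (iTF-Microglia) were left untreated or given 100 ng/ml lipopolysaccharide (LPS) and 20 ng/ml interferon-gamma for 24 h, with 3 libraries in each of the 4 groups. The sample titles of the stimulated cells give the LPS dose with another unit, and the ng/ml of the other label fields was used. Per the labels' protocols, libraries were made from poly-A RNA without strand information, so reads of overlapping or antisense genes cannot be told apart. FastQC, Trim Galore and Salmon on hg38 are named in the submitters' processing notes, with no versions; the annotation and the way transcript estimates were summed per gene are not given in the sources used here.

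The deposited table holds estimated counts per gene that the authors did not normalize; Salmon estimates need not be whole, and the deposited values are whole numbers only, so they had been rounded to whole numbers before deposit and were used as they stand. The table has 62646 entries. A symbol occurred more than once for 1525 of its entries, and these were kept as separate genes. Library totals ran from 19.0 to 28.1 M counts. After edgeR's filterByExpr on the 4 groups, 19001 genes were tested, of which 1729 carry an Ensembl identifier only and 177 a repeated symbol. Coordinates are from GENCODE annotation on GRCh38, matched by symbol, and need not be the annotation behind the counts. Counts cannot separate transcripts of the knocked-in factor cassette from those of the endogenous genes.

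Groups were taken from the labels. All 12 libraries entered 1 fit with 1 mean per group (edgeR 4.0.16 in R 4.3.3, TMM scaling, glmQLFit and glmQLFTest, 8 residual degrees of freedom), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 4 contrasts were untreated microglia against untreated iPSCs, stimulated against untreated microglia, stimulated against untreated iPSCs, and the difference between the last 2. Adjusted p-values of genes are from this quasi-likelihood test. Log2 changes are the fitted values. Their errors are approximate standard errors (SE), the absolute log2 change over the root of the F statistic, and their 95% intervals are built from these. Where a group has few or 0 counts, such errors and intervals are no measure of precision. Other errors are standard deviations (SD) over 3 libraries. CPM are edgeR's CPM values on TMM-scaled library sizes, except that pluripotency transcripts as percent of iPSC levels use library totals. Where every library of a group had 0 counts, a fold is a lower bound computed with 3 counts over the group; with 1 to 3 counts the ratio is given with its 95% Poisson interval. The Poisson intervals and lower bounds cover counting error only, since reads without molecular identifiers are not independent molecules. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

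Lists of 23 gene groups and 15 sets of cell type markers (550 symbols, 516 of them tested) were compared with all other genes by limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over the 144 tests of lists with at least 3 measured genes. Each list is also given as counts of genes past the threshold over all genes tested, and adjusted over the list alone. Some lists share members, and in bulk RNA a marker list names no cell population by itself. Camera was repeated with an estimated correlation, and fry, which does not set a list against other genes, was run. The groups, the 4 contrasts, the lists and the rule for named genes were fixed before the data were examined. The rule names 31 genes in every comparison, plus the 8 genes with the largest rise and the 8 with the largest fall (6 and 6 for the difference of responses) among those past the threshold, at 20 CPM or more in the higher group, with no overlap between the libraries of the 2 groups (not asked of the difference) and with a symbol that is not clone-based; in each list, members with the largest changes and the most abundant members that did not pass are examples. Any other gene is said to be chosen after its values were seen. Some genes under these rules are not reported here.

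Alternatives were RLE, upper-quartile and library-total scaling, other filters on low counts, DESeq2 1.42.0, limma-voom, stricter thresholds, a fit of the 2 groups alone, the replicate number as a block, and each library left out in turn. Families of genes by the start of their symbol, and a fit without 3 microglia libraries, were added after the data were seen. Every sample's counts were checked against those of its group, and no pair agreed within sampling noise (chi-square over degrees of freedom 3.27 at the lowest). The scripts were tested on simulated data made from the libraries' means and sizes, with 200 changed genes in each of 10 runs. The changed genes lay at 1 CPM or more in the untreated group and rose or fell at random. The real microglia response had 8998 genes called, so the rates below need not hold for it. For the microglia response, 85.8% of the genes changed 2-fold and 30.2% of those changed 1.25-fold were recovered, and 3.89% of calls were false. For the iPSC response, 81.2% and 24.2% were recovered, and 5.96% of calls were false. Figures were drawn with matplotlib 3.10.9.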

Results

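Transcript levels were measured in 12 libraries, 3 each of untreated iTF-iPSCs, iTF-iPSCs given LPS and interferon-gamma, untreated iTF-Microglia at day 18, and iTF-Microglia given the same stimuli for 24 h. Library totals were 22.1, 25.9 and 22.3 M counts in untreated iPSCs, 19.0, 19.3 and 27.4 M in stimulated iPSCs, 26.1, 24.7 and 27.2 M in untreated microglia, and 22.4, 28.1 and 21.0 M in stimulated microglia. The first principal component held 85.1% of the variance and separated the 2 cell types, and the second held 7.93%. FN1, which encodes fibronectin, took 6.27% ± 0.0613 (SD, n = 3) of the counts in untreated microglia and 0.167% ± 0.0295 in untreated iPSCs. Mitochondrially encoded transcripts took 0.907% ± 0.134 of the counts in untreated iPSCs and 1.86% ± 0.110 in untreated microglia. Replicate 2 of the stimulated microglia stood apart from its group, with a chi-square over degrees of freedom of 18.0 and 23.1 against the 2 other libraries of the group, where all other replicate pairs lay between 3.27 and 5.11.

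The first comparison asked what separated the factor-induced microglia from the cells they were made from. Untreated microglia held high levels of myeloid and microglial transcripts that iPSCs lacked, and had lost most of the pluripotency program. CSF1R (5:150053291-150113372, GRCh38), the receptor for the growth factor that microglia depend on, stood at 1221 ± 29.8 CPM (SD, n = 3) in microglia and 0.0709 ± 0.0636 in iPSCs. TREM2 (6:41158506-41163186), a lipid-sensing receptor of microglia, stood at 150 ± 4.25 and 0.0225 ± 0.0196 CPM, a count ratio of 6488 (95% Poisson interval 1796 to 53582). P2RY12, a purinergic receptor of resting microglia, stood at 151 ± 5.52 and 0.0123 ± 0.0212 CPM, a ratio of 13052 (2342 to 515566). Levels of LIN28A, an RNA-binding protein of pluripotent cells, fell from 2047 ± 82.8 to 14.9 ± 25.5 CPM. In all, 15709 of the 19001 genes differed (7508 higher and 8201 lower in microglia), and 10312 of these by at least 2-fold.

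Of the 27 microglia identity genes, 26 were higher in microglia and 1 was lower. C1QC, a subunit of the complement initiator C1q, was at least 22225-fold higher (770 ± 6.31 CPM against 0 counts). AIF1, the cytoskeletal protein IBA1, rose by 7.30 ± 0.11 on the log2 scale (SE), CX3CR1, the fractalkine receptor, by 8.96 ± 0.24, and TMEM119, a membrane protein used as a microglia marker, by 3.83 ± 0.22. The exception was SALL1, a transcription factor of brain microglia, which fell by 1.77 and stood at 57.8 CPM in microglia and 197 in iPSCs. All 23 general macrophage and myeloid genes were higher. Among them LYZ, which encodes lysozyme, reached 5761 ± 193 CPM, a ratio of 166463 (56960 to 807201), and the protease gene CTSS was at least 12116-fold higher. Other large rises were those of the chemokine CCL13 (at least 50754-fold), the complement receptor VSIG4 (at least 18156-fold), the immune receptor SLAMF8 (at least 12793-fold), the formyl peptide receptor FPR1 (at least 10279-fold) and the pore-forming protein MPEG1 (at least 10148-fold). Of 18 disease-associated microglia genes, 16 rose and 1, the fatty acid carrier FABP5, fell by 0.93, while the lipase LPL did not pass (-0.02). All 22 lysosome genes rose, among them CTSB by 5.35 and LIPA, the lysosomal acid lipase, by 4.56, as did 20 of 25 genes at Alzheimer's disease risk loci, where the others included the chaperone CLU (-2.56) and the ephrin receptor EPHA1 (-5.73). Camera placed these lists above other genes, with adjusted p = 1.03e-10 for identity, 3.87e-10 for myeloid, 6.59e-06 for disease-associated, 4.87e-10 for lysosome and 3.11e-05 for risk loci genes; with an estimated correlation the lysosome p was 0.0687 and the other 4 calls held.

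Among the 6 knocked-in factors, 5 were higher in microglia. SPI1 (11:47354860-47378576) stood at 69.7 CPM against 0.0973 in iPSCs. IRF5 rose by 6.98 ± 0.10, IRF8 by 2.41 ± 0.31 and CEBPA by 2.19 ± 0.14, while CEBPB fell by 0.93 ± 0.08. As a list they did not pass (camera adjusted p = 0.0579). They did in 5 of the 6 fits that left out 1 library, with adjusted p between 0.0411 and 0.0499, the exception being untreated microglia replicate 2. The counts cannot say whether these transcripts came from the cassette or from the endogenous genes.

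Of 30 pluripotency genes, 28 were lower in microglia (camera adjusted p = 7.63e-05, 0.642 with an estimated correlation). POU5F1 (6:31164337-31180731), which encodes OCT4, fell from 950 ± 26.9 to 10.2 ± 17.6 CPM (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 6.34e-04), NANOG from 58.1 ± 2.19 to 0.508 ± 0.843 and SOX2 from 341 ± 19.5 to 2.71 ± 3.59. The microglial level of POU5F1 lay almost wholly in replicate 3, at 30.6 CPM against 0.0442 and 0.0465 in the other libraries, and without replicate 3 the log2 changes of POU5F1, LIN28A, NANOG and SOX2 were -14.20, -13.82, -11.02 and -9.05. LEFTY2 and GDF3, both ligands of the TGF-beta family, did not pass (log2 -0.01 and -1.01). Other large falls were those of EOMES, a mesendoderm transcription factor (at least 529-fold), and of CST1, a cystatin protease inhibitor (ratio 3145, 870 to 25971). INHBE, an activin subunit, went from 134 to 0.0606 CPM and STC2, a secreted glycoprotein, from 298 to 0.590 CPM. The transcription factor SOX21 went from 94.6 to 0.186 CPM, the muscle actinin ACTN3 from 48.4 to 0.0987 CPM and the non-coding RNA RMST from 24.5 to 0.0564 CPM. CKMT1A, a mitochondrial creatine kinase, had a ratio of 479 (164 to 2325), made uncertain by a near-identical copy. Without untreated microglia replicate 3 the log2 changes of SOX21, ACTN3, CST1 and RMST were -10.33, -13.19, -14.13 and -12.21 in place of -8.91, -8.80, -11.38 and -8.58. Without replicate 2 those of CKMT1A and INHBE were -12.01 and -12.28 in place of -8.74 and -11.02. Cell cycle genes fell, 23 of 27 (BUB1 by 2.77, BIRC5 by 2.64), while PCNA and MCM5 did not pass (0.10 and -0.18; camera adjusted p = 0.00213, 0.717 with an estimated correlation). Of 9 mesoderm and endoderm markers 8 fell (camera adjusted p = 0.0245, and 0.524 with an estimated correlation), and of 10 neuron markers 8 fell and 1 rose (0.0409, and 0.158).

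**Figure D1:**
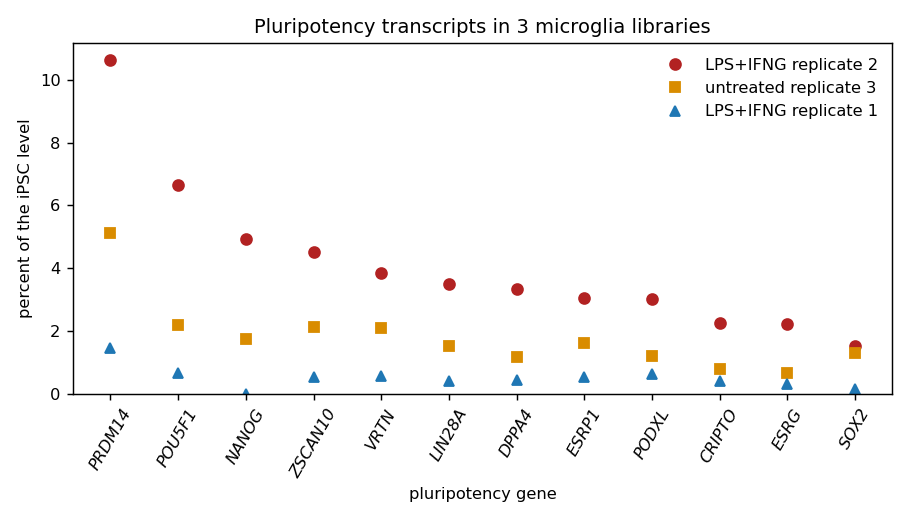
Level of 12 pluripotency genes in the 3 microglia libraries that held such transcripts (untreated replicate 3, stimulated replicates 1 and 2). Values are percent of the mean over untreated and stimulated iPSCs, on library totals without TMM scaling. The level in microglia libraries of the same treatment that nearly lacked such transcripts was subtracted first. Each point is 1 library. PRDM14 stands at 10.6% and SOX2 at 1.52% in stimulated replicate 2.

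Receptor and immune genes rose before any stimulus was given. All 11 LPS receptor pathway genes were higher in microglia. CD14, the LPS co-receptor, rose from 0.154 ± 0.0949 to 1141 ± 36.0 CPM, TLR4, the LPS receptor, by 7.18 ± 0.15, and LY96, its partner MD-2, by at least 238-fold. In the interferon-gamma receptor pathway 6 of 7 genes rose, among them IFNGR1 by 1.46 ± 0.06 and IFNGR2 by 2.92 ± 0.07, and SOCS1, a feedback inhibitor, fell by 1.75. Type I interferon-stimulated genes were higher in 25 of 30 cases and lower in 4, with SAMD9L at a ratio of 2067 (370 to 81686) and HERC6 down by 1.60. Of 30 interferon-gamma-induced genes 20 were higher and 6 lower. IRF1, an interferon-induced transcription factor, rose by 3.42 ± 0.12, CIITA, the regulator of MHC class II, by 5.41 ± 0.28, CXCL10 by at least 64.8-fold and CXCL9 by at least 93.3-fold, both chemokines. IDO1, a tryptophan-degrading enzyme, fell by 3.53 ± 0.20 and WARS1, a tRNA synthetase, by 2.43. The CXCL9 level of 3.22 ± 4.99 CPM came mostly from replicate 1 (8.97 CPM against 0.0465 and 0.635), and without it the log2 change of CXCL9 went from 9.29 to 6.13 and that of CXCL10 from 8.76 to 8.15. NF-kB and inflammatory cytokine genes rose in 27 of 35 measured cases and fell in 3. TNF was at least 296-fold higher and IL1B, the interleukin-1 beta gene, had a ratio of 5102 (1412 to 42136). IL6 (0.91, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0904) and CCL5 (0.0930 CPM in microglia, 0 counts in iPSCs, adjusted p = 0.0701) did not pass. Without untreated iPSC replicate 3 the adjusted p of IL6 was 0.0125, and without untreated microglia replicate 1 or 3 that of CCL5 was 0.0345 or 0.0324. MHC class I genes rose in 14 of 17 cases and fell in 2 (B2M, the shared light chain, up by 4.65). MHC class II genes rose in 11 of 14, with 3 lower (HLA-DRA up by 5.33, HLA-DOA down by 3.42). Inflammasome genes rose in 11 of 12, and AIM2, a DNA sensor, had a ratio of 25.3 (8.40 to 125) in favour of iPSCs. Complement genes rose in 9 of 16 cases and fell in 2 (C1R by 3.21, C1S by 1.70). Camera adjusted p were 1.07e-04 for the LPS pathway, 0.0215 for the interferon-gamma receptor, 3.16e-05 for type I, 0.0120 for interferon-gamma-induced, 1.46e-05 for NF-kB, 4.28e-04 for class I, 0.00852 for class II, 4.45e-04 for inflammasome and 0.00964 for complement genes. With an estimated correlation the inflammasome call held (adjusted p = 0.0323) and the others did not (p = 0.0687, 0.330, 0.130, 0.294, 0.248, 0.174, 0.366 and 0.157 in the same order).

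Sets of metabolic, stress and cell type genes filled out the comparison. Cholesterol synthesis genes rose in 20 of 22 cases (INSIG1, a sterol sensor, by 2.32) and fell in 1 (camera adjusted p = 5.42e-04, 0.325 with an estimated correlation). Cholesterol efflux genes were 7 up and 2 down of 10 (0.0583), with the transporter ABCG1 up by 5.61 and the lipoprotein gene APOE by 2.87. The p53 targets were 8 up and 2 down of 12 (CDKN1A by 4.78; 0.0722, and 0.0387 without untreated iPSC replicate 1). Stress response genes were 5 up and 8 down of 13 (ASNS, asparagine synthetase, down by 5.84; 0.396). Glycolysis genes were 10 up and 9 down of 19 (0.914) and oxidative phosphorylation genes 17 up and 5 down of 28 (0.0727). Both turned mostly lower with library-total scaling, to 6 up and 11 down and to 8 up and 16 down. Markers of granulocytes rose in 7 of 8 cases (S100A8 by at least 3772-fold; 0.00224, p = 0.0687 with an estimated correlation). Those of dendritic cells rose in 7 of 8 (camera adjusted p = 0.0145, and 0.284), of monocytes in 7 of 8 (7.22e-04, and 0.188) and of border-associated macrophages in 6 of 6 (the scavenger receptor CD163 reached 381 CPM; 0.00470, and 0.0687). These sets are not separate, as granulocyte and monocyte markers share S100A8 and S100A9. The myeloid list shares CD14 with the monocyte set and CD163 and MRC1 with the border-associated set. Fibroblast and mesenchyme markers were 8 up and 1 down of 11 (0.128), with the collagen COL3A1 at 564 CPM against 45.2 and THY1 down by 2.97. The other marker sets did not pass. Neural progenitor markers were 1 up and 3 down of 5 (0.622), astrocyte 3 up and 4 down of 7 (0.924), and oligodendrocyte 1 up and 3 down of 4 (0.594). Endothelium markers were 4 up and 3 down of 7 (0.718), hematopoietic progenitor 4 up and 2 down of 7 (0.439) and lymphocyte 4 up and 0 down of 6 (0.148). Of the sets too small for a set test, megakaryocyte and erythroid markers had 1 of 2 higher and mast cell markers 0 of 1 called. Adjusted over the list alone, the counts were the same in 37 of the 38 lists, the exception being the megakaryocyte and erythroid set with 1 up and 1 down. The shift common to all genes depended on the scaling. Relative to TMM the median log2 change moved by -0.30 with upper-quartile and by -0.51 with library-total scaling. The share of called genes that were higher, 47.8% with TMM, was 39.1% and 34.2%. Fitted log2 changes of genes with few counts in iPSCs shifted when 1 untreated iPSC library was left out. CSF1R was 14.92 without replicate 3, and SPI1 was 10.28 and 8.85 without replicates 1 and 2 in place of 9.48. Without replicate 1 CIITA was 6.09, IL1B 14.46 and P2RY12 14.81 in place of 5.41, 12.03 and 13.14.

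The second comparison asked how the microglia responded to LPS and interferon-gamma. Stimulated microglia raised interferon-induced chemokines from near 0 to some of the most abundant transcripts, and lowered several microglial receptors. CXCL9 rose from 3.22 ± 4.99 to 35534 ± 4349 CPM, CXCL10 from 2.23 ± 1.40 to 8626 ± 1056 CPM, and CXCL11 from 0.0591 ± 0.0254 to 1904 ± 255 CPM. All 3 are ligands of the chemokine receptor CXCR3, with genes side by side at 4:76001275-76007488, 4:76021117-76023497 and 4:76033682-76041415 (GRCh38). IDO1 (8:39902275-39928444) rose by 11.61 ± 0.22 on the log2 scale, to 4860 ± 378 CPM. TREM2 fell from 150 ± 4.25 to 1.51 ± 0.482 CPM, a log2 change of -6.61 ± 0.13, and CSF1R from 1221 ± 29.8 to 218 ± 5.59 CPM, a change of -2.49 ± 0.09. Of the 19001 genes, 8998 passed (4459 higher and 4539 lower), and 3018 of these changed by at least 2-fold.

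**Figure D2:**
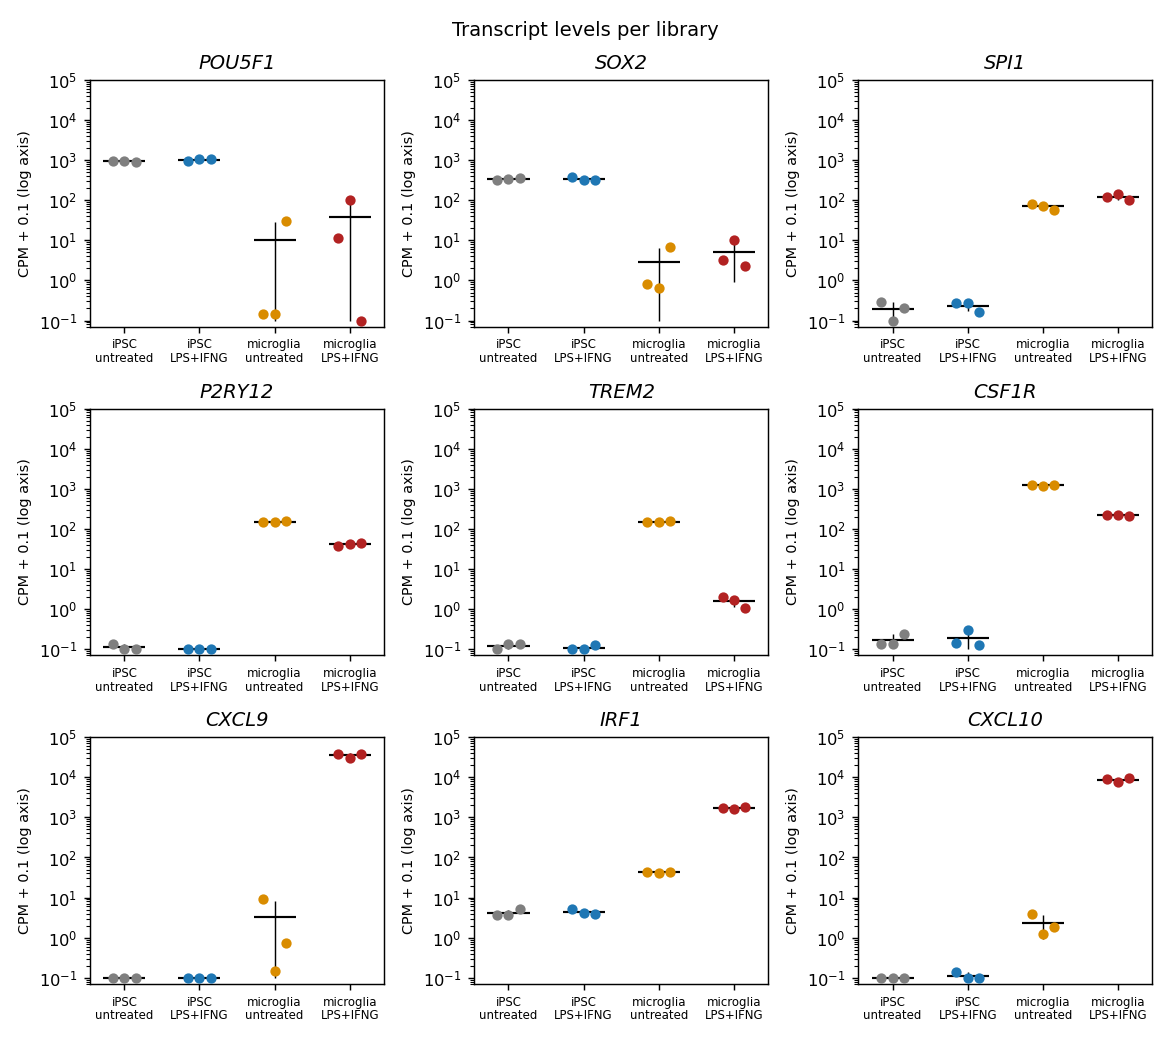
Level of 9 genes in each library, in CPM plus 0.1 on a log axis, by group (3 libraries each); points are libraries, lines are means and bars are SD. CXCL9 stands at 35534 CPM on average in stimulated microglia and TREM2 falls from 150 to 1.51 CPM, while POU5F1 in microglia reaches 30.6 CPM or more in only some libraries.

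All 30 interferon-gamma-induced genes rose, with a median log2 change of 5.71, as did all 30 type I interferon-stimulated genes, with a median of 3.22. Among the interferon-gamma-induced genes, the Fc receptor gene FCGR1A was called higher with TMM but not with RLE, upper-quartile or library-total scaling. GBP5, a guanylate-binding protein, rose by 11.35 ± 0.22 and IRF1 (5:132481609-132490798) by 5.33 ± 0.11. CIITA rose by 3.93 ± 0.14 and SOCS1 by 6.33. Among type I genes, IFI27 rose by 7.40 and ISG20, an exonuclease, by 5.80. All 17 MHC class I genes rose (PSMB9, an immunoproteasome subunit, by 6.13, the peptide transporter TAP1 by 5.93 and HLA-F by 5.10), as did all 14 MHC class II genes (HLA-DQA1 by 5.32, HLA-DOA by 4.52). Of 16 complement genes 14 rose and 1 fell (14 and 2 adjusted over the list alone), CFB, factor B, by 8.91 and C4B by 8.17, while the receptor C5AR1 fell by 2.21; C4A and C4B are near-identical, so that their separate values are uncertain. Camera adjusted p were 9.89e-26, 7.19e-21, 3.50e-18, 1.48e-11 and 3.06e-09 for these 5 lists, and all 5 calls held with an estimated correlation. UBD, a ubiquitin-like modifier, rose by 13.43 ± 0.27 and OR2I1P, an olfactory receptor pseudogene, by at least 16650-fold to 757 ± 143 CPM, but OR2I1P overlaps UBD in the genome, so its value is uncertain. CCL5, a T cell chemokine, rose to 277 ± 19.4 CPM from 0.0930 ± 0.161.

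Of 35 NF-kB and inflammatory cytokine genes 25 rose and 3 fell (28 and 3 adjusted over the list alone; camera adjusted p = 2.33e-12, 0.0709 with an estimated correlation). The apoptosis inhibitor BIRC3 rose by 7.32, the cytokine subunit EBI3 by 5.79, IL6 by 4.78 ± 0.34 and TNF by 2.05 ± 0.13. IL10, an anti-inflammatory cytokine, fell by 1.99, and the neutrophil chemokines CXCL1 and CXCL3 fell by 1.92 and 1.76. IL1B did not pass, at 140 ± 19.6 CPM against 118 ± 2.96 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0544); without stimulated microglia replicate 2 its log2 change of 0.25 became 0.35 with an adjusted p of 3.53e-04. In the interferon-gamma receptor pathway 5 of 7 genes rose and IFNGR1 fell by 0.49 ± 0.06, while IFNGR2 did not pass (-0.01; camera adjusted p = 0.00415, 0.248 with an estimated correlation). The LPS receptor pathway was split, 6 up and 4 down of 11 (0.686), with CD14 down by 0.72 ± 0.07, TLR4 by 0.51 ± 0.10 and the adapter TICAM2 up by 2.32. LY96 fell by 0.51 ± 0.18 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0421). This call was lost without untreated replicate 1, 2 or 3 or stimulated replicate 1 or 2 (adjusted p = 0.0723, 0.0925, 0.123, 0.107 and 0.101) and with the replicate number as a block (0.0799). Inflammasome genes were 5 up and 3 down of 12 (6 and 3 adjusted over the list alone; CASP4 up by 1.93, the sensor NLRC4 down by 1.85; 0.489).

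Microglia identity genes fell in 22 of 27 cases and rose in 3 (23 and 3 adjusted over the list alone; camera adjusted p = 6.83e-04, and the call held with an estimated correlation). CX3CR1 fell by 2.11 ± 0.13, TMEM119 by 1.96 ± 0.20, P2RY12 by 1.88 ± 0.08, the receptor GPR34 by 3.76 and AIF1 by 0.53 ± 0.07. The 3 that rose were the C1q subunits C1QA (2.15), C1QB (3.36) and C1QC (1.37), and DOCK8, a guanine exchange factor, did not pass (0.03). Disease-associated genes fell in 10 of 18 cases and rose in 3 (GPNMB by -4.47, osteopontin SPP1 by -3.78, the growth factor CSF1 up by 3.82, APOE not past the threshold at 0.11; camera adjusted p = 0.0225, 0.101 with an estimated correlation). Macrophage and myeloid genes were 7 up and 13 down of 23 (7 and 14 adjusted over the list alone; 0.0794). The scavenger receptor MSR1 fell by 4.07, the Fc receptor FCGR3A, which shares sequence with FCGR3B, by 3.45 and LYZ by 2.60, while CTSS rose by 2.30. Other large falls were those of VSIG4 (-7.48 ± 0.09) and the receptor LILRB5 (-5.93 ± 0.13). The membrane protein TMEM132E (-4.59 ± 0.15), the cell cycle inhibitor CDKN2C (-4.43 ± 0.22) and the proteoglycan SPOCK1 (-4.35 ± 0.11) fell as well. Markers of monocytes fell in 7 of 8 cases and rose in 1 (FCN1 by -3.98; 8.67e-04, p = 0.193 with an estimated correlation), and those of granulocytes in 6 of 8 with 1 up (MPO, myeloperoxidase, by -3.67; 0.00195, p = 0.0687). Of the knocked-in factors IRF8 rose by 3.20 ± 0.23, CEBPB by 2.65 ± 0.08 and SPI1 by 0.82 ± 0.13, CEBPA fell by 0.44 ± 0.13, and IRF5 did not pass (-0.03; list 0.557).

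Cell cycle genes fell in 25 of 27 cases (26 adjusted over the list alone), MKI67, a proliferation marker, by 2.77 and CENPF, a kinetochore protein, by 2.49 (camera adjusted p = 3.54e-09, 0.432 with an estimated correlation). Cholesterol efflux genes rose in 6 of 10 cases and fell in 1 (the oxysterol receptor NR1H3 by 4.50, ABCG1 by 1.31; 0.0120, p = 0.0832 with an estimated correlation). Stress response genes rose in 8 of 13 with 1 down (ATF3 by 4.63; camera adjusted p = 0.0327, and 0.299 with an estimated correlation). The stress call was lost without stimulated replicate 2 (0.0965). Endothelium markers fell in 5 of 7 cases (6 adjusted over the list alone; CDH5 by 2.38; 0.0373, p = 0.299 with an estimated correlation), a call lost without stimulated replicate 1 or 3 or untreated replicate 2 (0.0986, 0.144 and 0.0571). Genes at Alzheimer's disease risk loci were 6 up and 11 down of 25 (0.621), CLU by 4.16 and the membrane protein MS4A4A by -3.11. Glycolysis genes were 5 up and 10 down of 19 (hexokinase HK2 by -1.84; 0.266) and oxidative phosphorylation genes 6 up and 6 down of 28 (0.967). Lysosome genes were 10 up and 7 down of 22 (11 and 7 adjusted over the list alone; CTSH by 1.76, LIPA by -1.89; 0.586). Cholesterol synthesis genes were 8 up and 5 down of 22 (9 and 5 adjusted over the list alone; 0.496) and p53 targets 5 up and 2 down of 12 (the death receptor FAS by 2.36; 0.266). Under library-total scaling the lysosome, cholesterol synthesis and p53 lists turned mostly lower, to 6 up and 10 down, 5 up and 11 down, and 4 up and 5 down, and the LPS receptor, knocked-in factor and pluripotency lists were evenly split.

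The remaining sets did not pass. Pluripotency genes were 6 up and 2 down of 30 (3 and 2 adjusted over the list alone; 0.647), with LEFTY2 down by 2.13. POU5F1 stood at 11.1, 101.8 and 0 CPM in the 3 stimulated libraries (log2 1.90 ± 1.24, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.232). LIN28A (1.52 ± 1.26), NANOG (1.77 ± 1.15) and SOX2 (0.99 ± 0.68) did not pass either. Without untreated replicate 3 all 4 passed, at 9.59, 8.26, 6.03 and 3.11. Mesoderm and endoderm markers were 5 up and 0 down of 9 (0.249, and 0.0323 without stimulated replicate 3) and hematopoietic progenitor markers 0 up and 5 down of 7 (0.123, and 0.0412 without untreated replicate 3). Dendritic cell markers moved apart, 3 up and 5 down of 8 (LAMP3 by 7.16 and CCR7, a homing receptor, by 4.81, against CD1A by -5.83; 0.414). Counts up and down were 3 and 4 of 10 for neuron (0.868), 0 and 1 of 5 for neural progenitor (0.930), 2 and 1 of 7 for astrocyte markers (0.706). They were 0 and 1 of 4 for oligodendrocyte (0.185), 1 and 2 of 11 for fibroblast (0.938) and 1 and 4 of 6 for border-associated macrophage (1 and 5 adjusted over the list alone; 0.128). They were 0 and 4 of 6 for lymphocyte (0.128), 0 and 2 of 2 for megakaryocyte and erythroid, and 0 and 0 of 1 for mast cell markers. For lists with no second count, the counts adjusted over the list alone were the same. Median, mean and test differed in sign in 5 lists that did not pass. These were neuron (median 0.14, mean -0.11, test down), neural progenitor (-0.04, 0.33, down), fibroblast (-0.08, 0.14, down), Alzheimer's disease risk loci (0.00, -0.21, down) and oxidative phosphorylation genes (-0.03, 0.00, up). Library-total scaling moved the median of all genes by -0.20, and the share of called genes that were higher went from 49.6% to 28.2%. Without untreated replicate 1 the log2 change of CXCL9 was 16.60 in place of 13.42, that of CXCL10 12.52 in place of 11.91 and that of UBD 14.96 in place of 13.43. Without untreated replicates 2 and 3 that of CCL5 was 15.72 and 10.94 in place of 11.53.

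The third comparison gave the same stimuli to the undifferentiated cells. No gene passed in iPSCs by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 572 genes (3.01%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.326 for TGFBI, a matrix protein. DESeq2 called 3 genes, limma-voom 1, the fit of the 2 groups alone 6, and the test without a low-count filter 32. None of these genes was in the interferon, MHC or NF-kB lists, but TICAM2 of the LPS receptor pathway was called higher without the filter (log2 5.36, adjusted p = 0.0138), on 3, 0 and 14 counts in the stimulated libraries and 0 in the untreated ones. COL3A1 of the fibroblast list was called lower without the filter (-0.65) and with the 2 groups alone (-0.63). IRF1 (log2 0.08 ± 0.14, 95% interval -0.22 to 0.37) and IDO1 (0.06 ± 0.14) did not pass, IDO1 with 18.8 and 18.0 CPM. CXCL9, CCL5, TNF and LY96 had 0 counts in all 6 iPSC libraries. IFNGR1 (-0.01 ± 0.06) and IFNGR2 (-0.09 ± 0.07), at 36.7 and 30.2 CPM in untreated cells, and the factor CEBPB (0.06 ± 0.07) did not pass. POU5F1, at 1023 ± 39.6 against 950 ± 26.9 CPM, was not called (0.11 ± 1.05). The fit shares a gene's spread over all groups, so the error of a gene that varies between microglia libraries is widened in iPSCs. The fit of the 2 groups alone, which lacks this limit, did not call POU5F1 either.

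**Figure D3:**
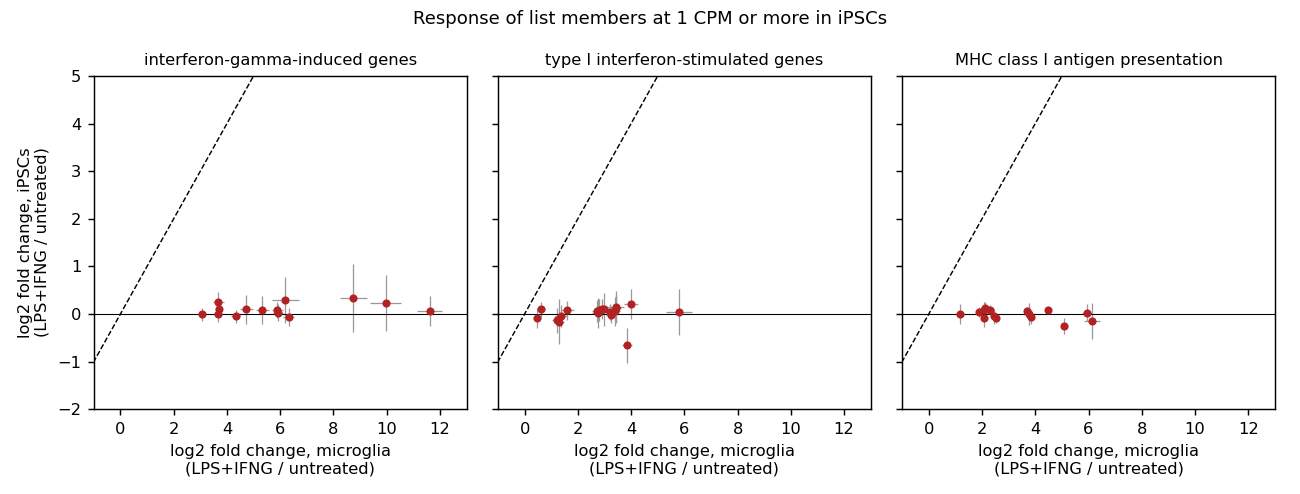
Log2 change with stimulation in iPSCs against that in microglia, for 14 interferon-gamma-induced, 19 type I interferon-stimulated and 15 MHC class I genes at 1 CPM or more in iPSCs; points are fitted values, bars are 95% intervals and the dashed line marks equal changes. Median upper bounds in iPSCs lie at 0.31, 0.31 and 0.17, against median changes of 5.61, 2.91 and 2.54 in microglia.

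For genes with enough counts to judge, the bounds in iPSCs were narrow. Over 14 interferon-gamma-induced genes at 1 CPM or more in iPSCs, the median upper 95% bound of the log2 change was 0.31, and 13 bounds lay under 1, the highest being that of GBP4 at 1.05. Over 19 type I genes the median bound was 0.31 and the highest was 0.53 for ISG20. Over 15 MHC class I genes it was 0.17 and the highest was 0.26 for HLA-E, and over 15 NF-kB genes it was 0.32, with 1.28 for IL23A. None of the 38 lists had a gene called; adjusted over the list alone, 1 p53 target rose. Camera placed 3 lists apart from other genes, with fibroblast markers lower (adjusted p = 0.0137), cholesterol synthesis genes lower (0.0384) and dendritic cell markers higher (0.0215). None of these calls held with an estimated correlation (p = 0.544, 0.599 and 0.299), and each was lost without stimulated replicate 1 (p = 0.0883, 0.256 and 0.0869). Cholesterol synthesis was also lost without stimulated replicate 3 or untreated replicate 2 or 3 (0.140, 0.119 and 0.392), and fibroblast without untreated replicate 3 (0.0565). The other 33 lists tested did not pass. Without untreated replicate 1, oxidative phosphorylation (0.00544) and p53 lists (5.64e-04) passed. Without stimulated replicate 1 oxidative phosphorylation (0.0490) and disease-associated genes (0.0288) passed, without stimulated replicate 3 Alzheimer's disease risk loci (0.0236), and without untreated replicate 2 monocyte markers (0.0481) passed while dendritic cell markers did not.

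The last comparison tested whether the response differed between the cell types. The change with stimulation was larger in microglia for interferon and antigen presentation genes, and more negative for several microglial genes. IRF1 rose by 5.25 ± 0.17 more in microglia on the log2 scale, CEBPB by 2.60 ± 0.11 and IDO1 by 11.55 ± 0.25. The cytokine IL32 rose by 11.20 ± 0.26 more, from 0.971 to 1915 CPM in microglia and from 1.61 to 1.34 CPM in iPSCs. All 17 MHC class I genes, 13 of 14 MHC class II genes, 26 of 30 type I and 24 of 30 interferon-gamma-induced genes rose more in microglia (17, 13, 28 and 25 adjusted over the list alone), and 25 of 27 cell cycle genes fell more. In all 6330 genes passed (3195 with the higher change in microglia and 3135 with the lower), and 2359 of these by at least 2-fold. For CXCL9, CXCL10, CCL5, TNF and LY96 the difference could not be estimated, as iPSCs held 0 or 1 counts. TREM2 (-5.91 ± 2.38, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0737) and P2RY12 (-0.19 ± 0.27, 0.649) did not pass, each with at most 2 counts per iPSC group. With so few counts the errors of these differences are no measure of precision. Without untreated microglia replicate 3 POU5F1 (9.48), LIN28A (8.22) and SOX2 (3.11) passed, and without stimulated microglia replicate 2 CEBPA passed (-0.53). Library-total scaling moved the median by -0.21 and the share of called genes with the higher change in microglia from 50.5% to 27.3%.

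Of the 38 lists, camera placed 16 apart in this comparison. Higher in microglia were the type I (adjusted p = 3.93e-23), interferon-gamma-induced (5.30e-29), MHC class I (2.87e-21), MHC class II (1.74e-12) and complement genes (2.70e-10; 8 up and 0 down of 16), and all 5 calls held with an estimated correlation. NF-kB genes were 16 up and 1 down of 35 (7.61e-14, p = 0.0679 with an estimated correlation), with BIRC3 up by 7.74 ± 0.67. The interferon-gamma receptor list was 5 up and 1 down of 7 (camera adjusted p = 0.00110, and 0.188), with SOCS1 up by 6.39 ± 0.13 and IFNGR1 down by 0.49. Cholesterol efflux genes were 6 up and 1 down of 10 (camera adjusted p = 0.0120, and 0.0832) and stress genes 6 up and 1 down of 13 (8 and 1 adjusted over the list alone; 0.0470, and 0.325). Lower in microglia were the identity genes, 0 up and 7 down of 27 (6 down adjusted over the list alone; 0.00258, held with an estimated correlation), among them TMEM119 by 1.55 ± 0.35. Disease-associated genes were 1 up and 8 down of 18 (1 and 9 adjusted over the list alone; camera adjusted p = 0.00408, and 0.0605). Myeloid genes were 0 up and 9 down of 23 (1 and 10 adjusted over the list alone; camera adjusted p = 0.0470, and 0.325) and cell cycle genes 0 up and 25 down of 27 (MKI67 by 2.71 ± 0.24; 4.41e-09, and 0.432). Endothelium markers were 0 up and 2 down of 7 (4 down adjusted over the list alone; camera adjusted p = 0.0476, and 0.325). Granulocyte markers were 0 up and 1 down of 8 (0 down adjusted over the list alone; camera adjusted p = 0.00106, and 0.0658) and monocyte markers 0 up and 2 down of 8 (6.35e-04, and 0.188). Of the identity genes 22 were called lower and 3 higher in stimulated against untreated microglia, and no list gene was called in iPSCs. Differences are poorly estimated for genes with few counts in iPSCs. Smaller counts here than in the microglia response therefore do not show that iPSCs shared it. The stress call was lost without stimulated or untreated iPSC replicate 1 (0.0636 and 0.0585), without stimulated microglia replicate 2 (0.123) and without untreated microglia replicate 1 (0.0572). The myeloid call was lost in 6 of the 12 fits that left out 1 library (0.0511 to 0.0784), and the endothelium call in 10 (0.0562 to 0.145). Both were also lost with RLE scaling (0.0566 and 0.0562).

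The other lists did not pass in this comparison. Counts up and down were 2 and 1 of 6 for the knocked-in factors (0.414), 4 and 1 of 30 for pluripotency (1 and 1 adjusted over the list alone; 0.756), 5 and 1 of 11 for the LPS receptor pathway (0.557), 2 and 3 of 12 for inflammasome genes (0.537). They were 7 and 4 of 22 for cholesterol synthesis (0.317), 3 and 7 of 19 for glycolysis (0.285), 4 and 3 of 28 for oxidative phosphorylation genes (0.762). They were 8 and 7 of 22 for lysosome (9 and 7 adjusted over the list alone; 0.762), 4 and 4 of 25 for Alzheimer's disease risk loci (0.414) and 4 and 1 of 12 for p53 targets (0.366). Under library-total scaling 5 of these turned mostly lower, to 1 and 2 for pluripotency, 4 and 7 for cholesterol synthesis, 2 and 10 for oxidative phosphorylation, 5 and 8 for lysosome and 3 and 4 for p53 genes. Marker sets gave 3 and 3 of 10 for neuron (0.826), 0 and 1 of 5 for neural progenitor (0 and 0 adjusted over the list alone; 0.963), 2 and 1 of 7 for astrocyte markers (0.718). They were 0 and 1 of 4 for oligodendrocyte (0.185), 1 and 1 of 11 for fibroblast (0.703), 0 and 2 of 7 for hematopoietic progenitor markers (0.240). They were 1 and 1 of 8 for dendritic cell (0.260), 0 and 2 of 6 for border-associated macrophage (0.147), 0 and 0 of 6 for lymphocyte (0.09996), and 2 and 0 of 9 for mesoderm and endoderm markers (0 and 0 adjusted over the list alone; 0.388). Megakaryocyte and erythroid markers had 0 and 1 of 2 (0 and 2 adjusted over the list alone) and mast cell markers 0 and 0 of 1. Median, mean and test differed in sign for the LPS receptor (0.47, -0.07, up), neuron (0.01, -0.10, down) and neural progenitor lists (0.01, 0.36, down).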

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

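All tests of explanations below, the counts over splits of the libraries included, were set after the result was seen. The items listed are those where the response of microglia differed from that of iPSCs.

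The response differed between the cell types for 6330 genes. Interferon and signalling genes rose more in microglia, with log2 differences of 5.25 for IRF1, 3.40 for IRF8, 2.60 for CEBPB, 3.22 for CIITA, 11.55 for IDO1, 11.20 for IL32, 6.12 for IL6, 14.78 for CXCL11, 14.96 for GBP5, 15.88 for UBD and 21.40 for OR2I1P, which overlaps UBD. Lower changes in microglia were found for CSF1R (-2.78), the marker TMEM119 (-1.55), the receptor IFNGR1 (-0.49), the lectin CLEC7A (-4.35), the peptide receptor FPR2 (-4.48), the inhibitory receptor LILRB5 (-6.33), TMEM132E (-4.65) and the amplifying receptor TREM1 (-5.21). For genes near 0 in iPSCs these fitted values depend on the prior count and are no bound. FPR2 stood at 46.1 and 46.3 CPM in untreated and stimulated microglia and at 0 and 0.122 CPM in iPSCs, so that its difference came from iPSCs. For UBD, GBP5 and IL6 the difference was larger than the rise in microglia (UBD 15.88 against 13.43). Part of these differences thus came from iPSCs, where no gene was called. Leaving out 1 library moved several of the fitted differences. CSF1R was -1.59 (adjusted p = 0.414) without stimulated iPSC replicate 2 and -3.71 without untreated iPSC replicate 3. TREM1 had adjusted p = 0.0861 and 0.0743 without stimulated iPSC replicates 1 and 3, and UBD was 13.43 and not called without untreated iPSC replicate 3. CIITA was 2.54 without untreated iPSC replicate 1, CLEC7A -6.00 and -3.72 without untreated and stimulated iPSC replicate 2, CXCL11 17.31 and 14.12 without stimulated iPSC replicates 1 and 3, FPR2 -3.85 without stimulated iPSC replicate 1, GBP5 14.26 and IL6 5.48 without untreated iPSC replicate 3, LILRB5 -7.01 and OR2I1P 20.55 without untreated iPSC replicate 1, and UBD 17.42 without untreated microglia replicate 1.

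Camera set 16 lists apart in the same comparison. Adjusted p were 5.30e-29 for interferon-gamma-induced, 3.93e-23 for type I, 2.87e-21 for MHC class I, 1.74e-12 for MHC class II, 7.61e-14 for NF-kB, 2.70e-10 for complement, 0.00110 for interferon-gamma receptor, 0.0120 for cholesterol efflux and 0.0470 for stress genes, all higher. They were 4.41e-09 for cell cycle, 0.00258 for identity, 0.00408 for disease-associated, 0.0470 for myeloid, 0.0476 for endothelium, 0.00106 for granulocyte and 6.35e-04 for monocyte genes, all lower. With an estimated correlation 6 of the 16 calls held, those of interferon-gamma-induced, type I, MHC class I, MHC class II, complement and identity genes. The others were lost, with camera adjusted p of 0.0679 for NF-kB, 0.188 for interferon-gamma receptor, 0.0832 for cholesterol efflux, 0.325 for stress, 0.432 for cell cycle, 0.0605 for disease-associated, 0.325 for myeloid, 0.325 for endothelium, 0.0658 for granulocyte and 0.188 for monocyte genes.

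Stimulated iPSCs had no gene called. Too little precision is argued against by a median upper bound of 0.308 over 14 interferon-gamma-induced genes. A lack of the LPS part would be consistent with the receptor chain, whose lowest member LY96 had 0 CPM. For interferon-gamma a missing transcript was taken as one under 1 CPM, but the lowest of the 5 members of the chain, JAK2, stood at 9.12 CPM. This argues against an absent transcript in that chain. JAK2 lay under the limit of 10 CPM set for a full chain, so a reduced level stays open. An exchange of names within the iPSCs is argued against, as no other split of the 6 libraries gave more than 1 gene, while a stimulus that did not reach the cells would give 0 called genes as found and stays open.

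The fall of identity genes in stimulated microglia could reflect a lower share of myeloid cells. A lower share alone would put the 22 falls close to 1 value, but for 19 the interval left out the median fall of -0.85. This argues against a lower share as the whole cause, while a part of it in the falls stays open. The 3 other scalings gave 23 called lower at the fewest, but all 3 move changes downward relative to TMM and decide nothing. Scaling as the whole cause is argued against by the same 19, since it shifts all genes alike. The 3 libraries with pluripotency transcripts are argued against by their low share of those transcripts. Over all members used and on library totals, the highest share was 3.49% of the iPSC level, in stimulated replicate 2. Single members stood higher there, PRDM14 at 10.6% and POU5F1 at 6.63%, and shares of TMM-scaled CPM would be higher. Fits that left out each of the 3 libraries in turn called 20, 20 and 22 lower (21 without all 3, with 1 stimulated microglia library left).

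The count of 15709 for differentiation was met by 1 of the 10 splits of its libraries, the real one, with at most 1 gene in any other. That of 8998 for the microglia response was met by 1 of 10, the highest other giving 14, and that of 0 for iPSCs by all 10, the highest other giving 1. For these, 10 splits are too few for a share under 0.05. For the difference of responses, 2 of 100 splits, the real one included, reached the 6330 genes, the highest other giving 6435. The 12 splits that kept the real microglia groups gave 6162 to 6435 genes and the other 88 at most 1, so the count rested on the microglia groups, whose 10 splits are too few for a share under 0.05.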

How the results depend on the processing

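Called genes for differentiation went from 15709 to 10312 at a fold of at least 2 and to 8841 with glmTreat, for the microglia response from 8998 to 3018 and 1574, and for the difference of responses from 6330 to 2359 and 962, as these ask for larger changes by construction. For iPSCs, 0 became 32 without a low-count filter, 3 with DESeq2, 1 with limma-voom, 6 with the 2 groups alone and 1 each without stimulated iPSC replicate 1 (C7orf25) and 2 (ENSG00000278996), and the cause was not tested. Leaving out 1 library gave 15312 to 15514, 8003 to 9485, 0 to 1 and 5524 to 7476 genes, the highest difference being without stimulated microglia replicate 2. With the replicate number as a block the counts were 15538, 8464, 0 and 5805. That block moved LY96 in the microglia response to an adjusted p of 0.0799 and the cholesterol synthesis list in iPSCs to 0.0619. Fry called several lists that camera did not. Among them were knocked-in factors (fry adjusted p = 7.99e-11) and p53 targets (4.48e-08) for differentiation, and myeloid genes (2.43e-05) for the microglia response. In iPSCs, fry lost the camera calls of fibroblast (0.449), cholesterol synthesis (0.404) and dendritic cell lists (0.310). Without the 3 libraries with pluripotency transcripts, a test added later, the counts were 16097, 7953 and 6630. The last 2 rest on 1 stimulated microglia library, with the spread taken from the other groups, and the identity and myeloid lists of the difference went to camera adjusted p of 0.0573 and 0.201. Of the differentiation calls, 550 took the other direction with library-total scaling and 68 with upper-quartile scaling, and 1 call of the microglia response did so without the 3 libraries. With simulated changes of 1.5, 2 and 4-fold in genes at 1 CPM or more, the test recovered 65.6%, 85.8% and 95.2% in microglia and 65.2%, 81.2% and 97.6% in iPSCs. Part of the changes was missed at each of these folds. Depth and the number of libraries were not varied, so their part in this was not tested.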

Other observations

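All tests below were set after the result was seen, except the correlation across genes outside the pluripotency list, which was set before. The gene families and the genes in them were chosen after their values were seen.

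Further gene families moved together in stimulated microglia. Several families in this section share members with the lists above, so they are not independent of them. Among the shared genes are CCL8 of the NF-kB list, APOL3 of the interferon-gamma-induced list and PARP14 of the type I list. Of 17 CC chemokine genes 14 rose and 0 fell (camera adjusted p = 5.06e-08, held with an estimated correlation at 0.0332), among them CCL22, a ligand of regulatory T cells, by 6.45 and CCL8 by 4.13. All 5 apolipoprotein L genes rose (6.36e-06, held at 0.0433), with APOL3 by 8.71 and APOL1, the trypanosome lytic factor, by 5.48. Proteasome subunits, some shared with the MHC class I list, rose in 30 of 46 cases and fell in 2 (1.10e-06, held at 0.0433), and in 16 and 10 with library-total scaling. PARP genes rose in 9 of 13 cases with 1 down (4.57e-04, p = 0.0769 with an estimated correlation), PARP14 by 3.25 and PARP9 by 2.45. Fc receptor genes fell in 8 of 11 cases with 1 up (0.00136, held at 0.0433), FCGR2B by 1.46 and FCGRT, the neonatal Fc receptor, by 1.01. With RLE, upper-quartile or library-total scaling 8 fell and 0 rose. Cytosolic ribosomal protein genes fell in 50 of 76 cases with 0 up (camera adjusted p = 3.70e-06, and 0.652 with an estimated correlation).

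In the comparison of untreated microglia with iPSCs, all 10 leukocyte immunoglobulin-like receptor genes were higher (1.10e-04, held with an estimated correlation at 0.0433), as were 9 of 10 Toll-like receptor genes (3.95e-04, held at 0.0412) and 8 of 9 sialic acid lectin genes (0.00157, held at 0.0433). Aminoacyl-tRNA synthetase genes were lower in 15 of 17 cases and higher in 1 (camera adjusted p = 2.94e-04, and 0.319 with an estimated correlation), and zinc finger genes in 258 of 451 with 111 higher (0.00219, held at 0.0433).

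Pluripotency transcripts stood in 3 of the 6 microglia libraries. Shares of the iPSC level over all 12 members used were 1.38% in untreated replicate 3, 0.479% in stimulated replicate 1 and 3.49% in stimulated replicate 2. They use library totals and the mean of all iPSC libraries, less the level in microglia libraries that nearly lacked such transcripts. Mean TMM factors were lower in microglia (0.869 untreated, 0.753 stimulated) than in iPSCs (1.23 and 1.24), so shares of TMM-scaled CPM would be higher. Unchanged iPSC RNA mixed in at 1 share would put all members at that share. In each library the intervals of at least 7 of the 12 members left it out. These intervals cover counting error only, and replicate pairs differed by more (chi-square over degrees of freedom 3.27 at the lowest). In stimulated replicate 2 mixing at 1 share is argued against by the gap between PRDM14 at 10.6% and SOX2 at 1.52%. For the other libraries the number of members outside does not decide it. Residual cells of 1 altered state at different shares could give the same order of genes in each library, and across 33 genes outside the list the levels in untreated replicate 3 and stimulated replicate 2 had a Spearman rho of 0.737. The counts cannot say whether these were cells or ambient RNA.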
